A study of Homo sapiens with 33 samples.

How the data were processed

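Polyadenylated RNA was sequenced from cardiac myocytes made by differentiating WTc human induced pluripotent stem cells. Per the submitters' protocol, 3 siRNA oligos per target were pooled and delivered with a lipid reagent at 10 uM on day 0, the medium was changed 48 hours later, and a second dose was given on day 5 for 48 hours. The labels name 9 targets, a scrambled control (SCR) and a non-transfected control (NOSI), each with 3 libraries, and the 33 libraries were grouped by these labels. Sample titles also carry a field p1 (18 libraries of 6 targets) or p2 (15 libraries of 3 targets and both controls), whose meaning is not given in the sources used here.

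The deposited table holds counts of reads or read pairs per gene, without normalization. Per the submitters' processing notes, reads were aligned to hg19 with STAR 2.5.2a and counted with HTSeq 0.6.1, and the counting options and the annotation release are not given in the sources used here. The values were checked to be whole numbers for 63677 genes in each library beside 5 summary lines, and no 2 libraries were identical. Symbols were added by gene identifier from another annotation, which matched 52181 genes, and the unmatched ones held 0.771% of the counts.

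Depth ran from 7824746 to 10019987 counts in genes per library (median 9047254), so 3 counts correspond to 0.299 to 0.383 CPM. Libraries of the same group differed by a chi-square of 1.24 to 10.6 per degree of freedom. After edgeR's filterByExpr 16419 genes were tested, which hold 99.8% of the counts. With TMM normalization, edgeR 4.0.16 fitted 1 mean per group over all 33 libraries by quasi-likelihood (R 4.3.3). The common biological coefficient of variation was 5.43% and the prior degrees of freedom were 16.3. P-values were adjusted by Benjamini-Hochberg within each comparison at 0.05.

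Each target was compared with SCR, SCR with NOSI, and the mean of the 9 targets with SCR. Further results were the change of each target in the 8 other knockdowns, the genes changed the same way in at least 5 of the 9, the correlation of fold changes between knockdowns, and each target against the mean of the other targets with the same title field. Written before the data were examined were 44 gene lists with 862 entries, of which 5 entries matched no gene, and 43 lists with at least 3 tested members were tested. The test was camera on voom values (limma 3.58.1) with a preset correlation of 0.01, adjusted over 430 tests of 10 comparisons, and the lists of the mean of the 9 were adjusted by themselves. Alternatives were camera with an estimated correlation, fry and, for the lists that hold a target, camera without the silenced gene.

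Genes were named by a rule also written before the data were examined. It takes the target and other targets that pass, then the 7 highest and 7 lowest log2 fold changes among genes that pass, reach 5 CPM in the higher group and have all 3 libraries of one group above the other's. Left out there are unnamed clones, antisense and read-through transcripts, pseudogenes, Y-linked genes and XIST. Last come up to 3 members with the smallest adjusted p of each list that was called or had 3 members past the gene test. For genes shared by many knockdowns the 7 highest and 7 lowest mean log2 fold changes are named. Some genes taken by the rule are not reported here.

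The alternatives planned before the data were examined were DESeq2 size factors, no filter, the replicate number as a block, limma-voom, the DESeq2 1.42.0 Wald test, NOSI as the control, the other targets of the same title field as the comparator, a fit on the 6 libraries compared, only the 3 p2 targets for the mean, and leaving out each library in turn. The alternatives for targets in other knockdowns, for differences within a title field and for lists without the silenced gene were chosen after seeing the data. In counts simulated for COPS2 against SCR, 50 genes were changed per size. EdgeR called 13, 24, 39 and 47 at 1.25, 1.5, 2 and 4-fold, with 6 false calls. Camera called the 1 shifted list and 0 others in 430 tests, but lists of correlated genes were not simulated.

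Off-target effects of the oligos were searched in 3′ untranslated regions. For each of 15987 words of 7 bases found in at least 100 genes, fold changes were regressed on the word's presence given the length and GC content of the region and the expression level, in 12969 genes with a region of at least 50 bases. The oligo sequences were not used here. On simulated data a planted shift of 0.15 was found in 10 of 10 rounds with 0 false words. To see what a shared control alone gives, groups and a control without change were simulated in 20 rounds.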

Results

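RNA was measured in cardiac myocytes derived from WTc, an established human induced pluripotent stem cell line, after knockdown of 1 of 9 nuclear or transcription regulators with small interfering RNA (siRNA). The targets were COPS2, HAND1, HMGB2, IRX4, MEF2C, NKX2-5, SKIDA1, SOX11 and ZFPM2. A scrambled siRNA (SCR) served as the transfected control and cells without siRNA (NOSI) as the non-transfected control, with 3 libraries in each of the 11 groups and 33 libraries in all. Cells received siRNA on day 0 and again on day 5 and were lysed on day 10. Levels are CPM (counts scaled to library size by TMM) as mean ± SD, log2 fold changes are given ± SE, and n = 3 libraries on each side where a target is compared with SCR or NOSI, or SCR with NOSI. A gene rose or fell where its adjusted p from edgeR was under 0.05 over all 16419 tested genes. A list rose or fell where camera's adjusted p was, and where no count adjusted over the list alone is printed it equalled the count over all genes. Genes given as highest or lowest are so among genes that passed, reached 5 CPM in the higher group and had all 3 libraries of one group above the other's, clones, antisense transcripts and pseudogenes aside, and the ranks are not complete. The labels do not say whether the 3 libraries of a group were separate cultures, so the p-values measure the spread between these libraries.

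Every siRNA was followed by a lower level of its own target, which ranged from 4.76% of the SCR level for COPS2 to 54.6% for SKIDA1. In each knockdown, all 3 libraries lay below every other library of the study for that target. COPS2 (ENSG00000166200), a subunit of the COP9 signalosome, was at 5.22 ± 0.390 CPM against 109.8 ± 1.89 in SCR (log2 fold change -4.39 ± 0.085, adjusted p = 1.05e-32). HMGB2 (ENSG00000164104), a chromatin protein abundant in dividing cells, was at 9.06 ± 0.589 against 167 ± 6.62 CPM (-4.20 ± 0.096, adjusted p = 4.68e-30). The cardiac factors NKX2-5 (ENSG00000183072), HAND1 (ENSG00000113196) and MEF2C (ENSG00000081189) were at 34.6 ± 5.32, 7.74 ± 1.02 and 10.2 ± 0.967 CPM against 313 ± 5.53, 67.4 ± 2.06 and 83.6 ± 2.42 in SCR. Their log2 fold changes were -3.17 ± 0.097 (adjusted p = 7.67e-26), -3.12 ± 0.10 (adjusted p = 3.32e-25) and -3.04 ± 0.093 (adjusted p = 1.31e-25). SOX11 (ENSG00000176887), a progenitor factor of the SOXC family, was at 3.20 ± 0.277 against 24.4 ± 3.95 CPM (-2.93 ± 0.15, adjusted p = 4.41e-18). IRX4 (ENSG00000113430), a ventricular factor, kept 25.2% of its SCR level (12.9 ± 0.15 against 51.3 ± 3.21 CPM, -1.99 ± 0.099, adjusted p = 5.05e-19). ZFPM2 (ENSG00000169946), a cofactor of GATA factors also called FOG2, kept 27.7% (19.0 ± 1.35 against 68.5 ± 3.17 CPM, -1.85 ± 0.074, adjusted p = 8.49e-23). SKIDA1 (ENSG00000180592), a little-studied nuclear protein, was at 8.62 ± 1.58 against 15.8 ± 1.12 CPM, which leaves 54.6% with a 95% range of 45.4 to 65.5% (-0.87 ± 0.13, adjusted p = 1.94e-05).

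**Figure D1:**
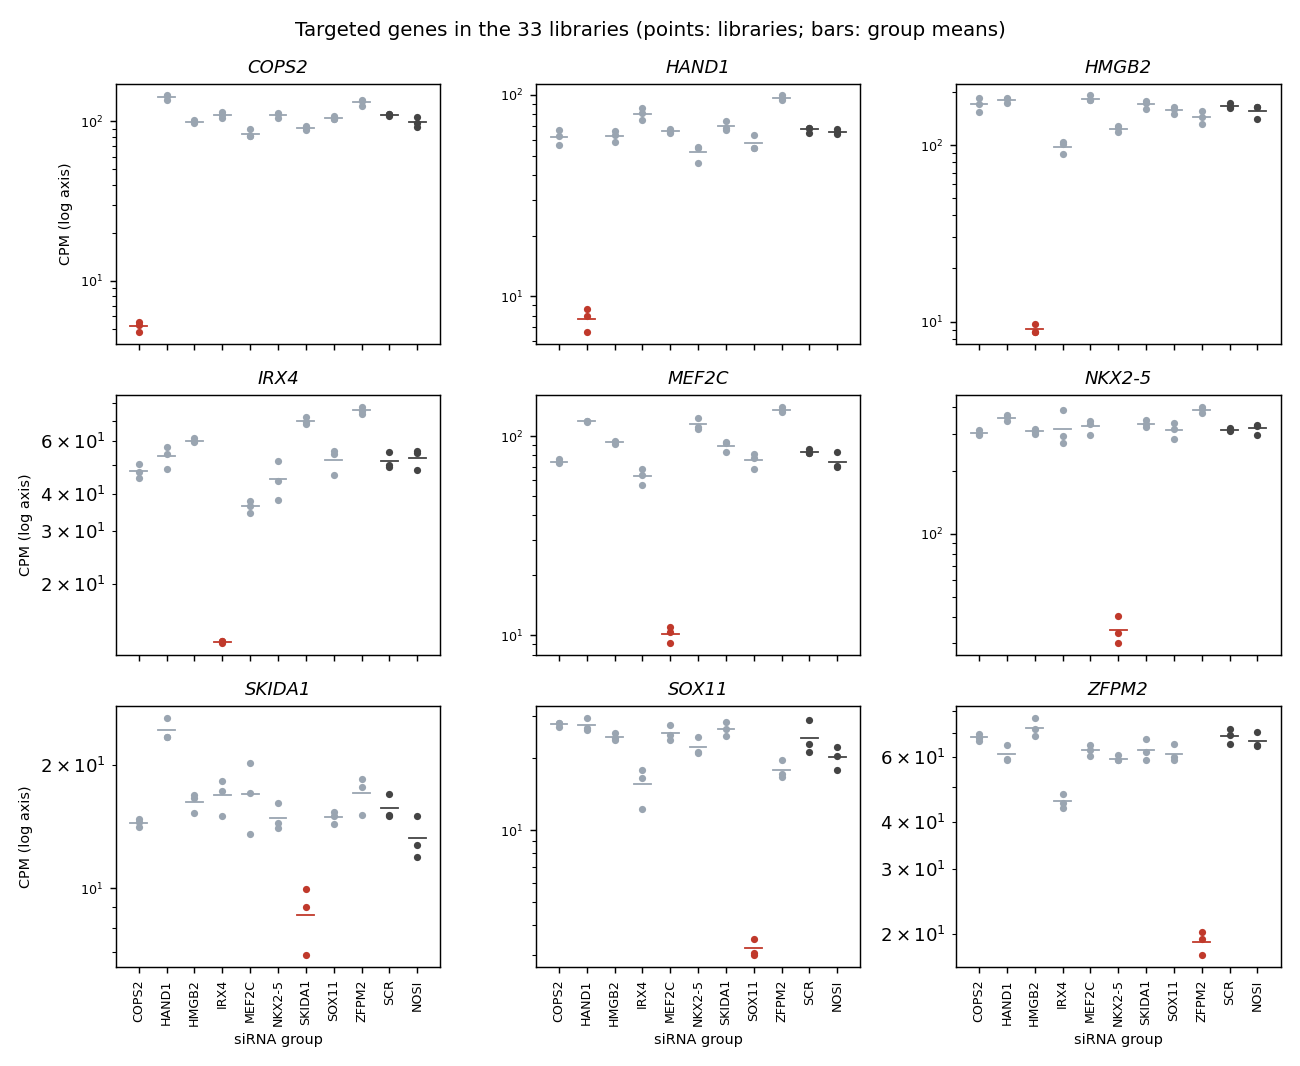
Level of each targeted gene in all 33 libraries, in CPM on a log axis, with 1 panel per target, the 11 groups along the horizontal axis, points for libraries and bars for group means. In each panel the 3 libraries of the matching knockdown are the lowest, from 3.20 CPM on average for SOX11 to 34.6 CPM for NKX2-5.

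Some targets also changed when another was knocked down. Of the 72 pairs of a target and another knockdown, 27 passed the test over all genes, 15 lower and 12 higher (28 when adjusted over the 72 pairs alone). In the IRX4 knockdown HMGB2 (-0.77 ± 0.070), SOX11 (-0.64 ± 0.11), ZFPM2 (-0.59 ± 0.064) and MEF2C (-0.41 ± 0.070) fell. IRX4 itself fell in the MEF2C knockdown (-0.50 ± 0.085) and rose in the SKIDA1 (0.45 ± 0.078) and ZFPM2 knockdowns (0.56 ± 0.078). MEF2C rose in the ZFPM2 (0.70 ± 0.067), HAND1 (0.50 ± 0.067) and NKX2-5 knockdowns (0.45 ± 0.067), SKIDA1 rose in the HAND1 knockdown (0.63 ± 0.11), and HAND1 rose in the ZFPM2 knockdown (0.52 ± 0.071) and fell in the NKX2-5 knockdown (-0.37 ± 0.074). These pairs were picked after their values were seen.

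**Figure D2:**
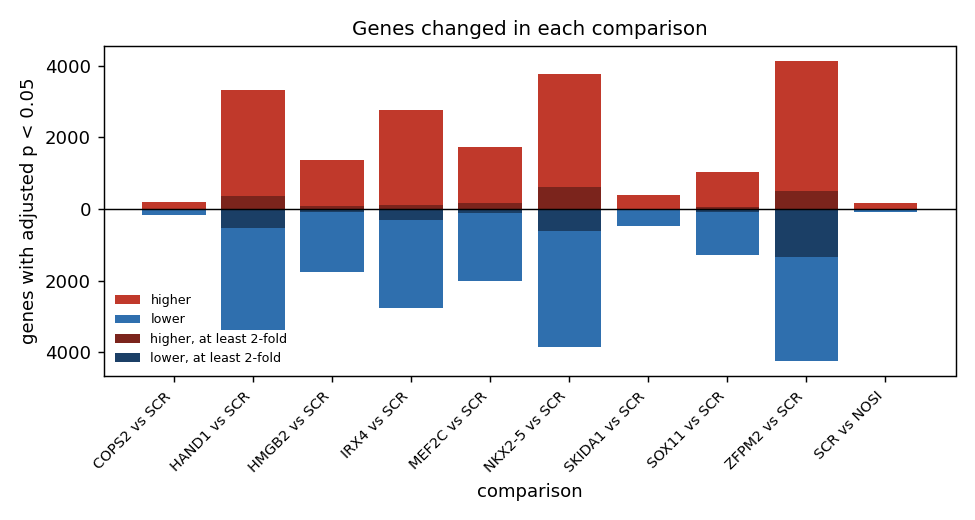
Genes that rose or fell in each comparison at an adjusted p under 0.05 in edgeR, as bars above (higher) and below (lower) an axis line at 0, with darker parts for changes of at least 2-fold. The counts run from 240 for SCR against NOSI and 355 for COPS2 to 8379 for ZFPM2.

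The ZFPM2 comparison asks which genes depend on this GATA cofactor, and it gave the largest response of the 9. ZFPM2 itself ranked 406 by lowest fold change, and off-target effects (below) may explain part of the falls. Every measured gene of the G2/M and mitosis list fell (26 fell of 26, median -2.15, camera adjusted p = 1.30e-24, or 0.0114 with an estimated correlation). TOP2A, which untangles chromosomes, was at -2.23 ± 0.067 (149 ± 4.80 to 31.7 ± 1.06 CPM), the cytokinesis gene ANLN at -2.09 ± 0.066 and the mitotic kinesin KIF23 at -2.58 ± 0.10. Genes of G1/S and DNA replication fell as well (2 rose and 21 fell of 24, median -0.97, camera adjusted p = 2.64e-10, or 0.147 with an estimated correlation). Among them were RRM2 (-1.90 ± 0.11), PCNA (-1.09 ± 0.068) and CDC6 (-1.77 ± 0.11). Cardiac stress markers fell (13 fell of 15, median -0.54, camera adjusted p = 1.40e-05, or 0.292 with an estimated correlation). Among them were XIRP2 (-3.02 ± 0.16), ANKRD1 (-1.23 ± 0.079) and NPPB, which encodes B-type natriuretic peptide (-1.64 ± 0.13). Cardiac transcription factors mostly rose (20 rose and 3 fell of 27, 21 rose and 3 fell adjusted over the list alone, median 0.52, camera adjusted p = 0.000141, or 0.102 with an estimated correlation), also without ZFPM2 (median 0.52, camera adjusted p = 1.16e-05, or 0.0479 with an estimated correlation), although GATA6, a partner of ZFPM2, fell (-1.12 ± 0.054), while the progenitor factor ISL1 rose by 1.18 ± 0.068. Atrial-enriched genes rose (8 rose and 1 fell of 13, 8 rose and 2 fell adjusted over the list alone, median 0.46, camera adjusted p = 0.00416, or 0.0508 with an estimated correlation). TBX5 was at 0.72 ± 0.044 and HEY1 at 2.06 ± 0.15.

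The genes with the highest fold changes were ADCY8, an adenylyl cyclase (4.47 ± 0.34, 0.257 ± 0.0590 to 5.97 ± 1.55 CPM), the noradrenaline transporter gene SLC6A2 (4.24 ± 0.30) and NGFR, a neurotrophin receptor (3.77 ± 0.23). Next were the potassium channel gene KCNJ10 (3.65 ± 0.31), DPP10 (3.52 ± 0.36), RASL10A (3.33 ± 0.29) and RAPGEF5 (3.23 ± 0.21). The lowest were GSG1 (-4.60 ± 0.34, 9.96 ± 2.13 to 0.403 ± 0.207 CPM), TXNDC16 (-3.40 ± 0.20) and the lipid phosphatase gene MTMR6 (-3.32 ± 0.11). Next were the sorting receptor gene SORL1 (-3.16 ± 0.26), PLXNC1 (-3.12 ± 0.17), skeletal actin ACTA1 (-3.06 ± 0.27) and the integrin gene ITGA10 (-3.03 ± 0.11). The SCR level of ADCY8 lies below that of 3 counts in a library (0.299 to 0.383 CPM), so its fold change is uncertain in size. TXNDC16 and PLXNC1 carry in their 3′ untranslated regions (3′ UTRs) the 7-base word TACAACT, whose carriers were lower as a group after this siRNA. The contractile genes MYL2, ventricular myosin light chain (-2.64 ± 0.16), and TNNI3, cardiac troponin I (-2.24 ± 0.12), fell, while the sarcomere list as a whole was not called. Cholesterol synthesis genes fell (2 rose and 14 fell of 21, 3 rose and 15 fell adjusted over the list alone, median -0.40, adjusted p = 0.00234) and BMP targets rose (7 rose of 13, median 0.33, adjusted p = 0.00659). Skeletal muscle genes fell (4 fell of 6, median -1.08, adjusted p = 0.00891) and oxidative phosphorylation genes rose (19 rose and 3 fell of 37, 20 rose and 3 fell adjusted over the list alone, median 0.15, adjusted p = 0.0101). Notch targets rose (6 rose of 9, median 0.66, adjusted p = 0.0111) and collagen and fibroblast genes rose (11 rose and 3 fell of 21, median 0.49, adjusted p = 0.0197). Ribosomal proteins rose (14 rose and 1 fell of 33, median 0.17, adjusted p = 0.0338). Their adjusted p ran from 0.185 to 0.816 with an estimated correlation. In the BMP and Notch lists ID1 rose by 2.53 ± 0.16 and JAG1 by 1.97 ± 0.084, and in the collagen and fibroblast list VIM rose by 1.33 ± 0.064. In all 8379 genes passed, 4127 higher and 4252 lower, 1822 by at least 2-fold.

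NKX2-5 is a homeodomain factor of early heart development, and its comparison asks which heart genes need it. Sarcomere genes fell (1 rose and 20 fell of 25, 1 rose and 21 fell adjusted over the list alone, median -0.60, camera adjusted p = 6.12e-12, or 0.205 with an estimated correlation). The Z-disc actinin ACTN2 was at -1.39 ± 0.045, desmin DES at -1.91 ± 0.084 and MYL3 at -1.65 ± 0.094 (699 ± 68.6 to 223 ± 20.3 CPM). Genes of natriuretic and secreted cardiac factors fell (8 fell of 9, median -0.53, camera adjusted p = 3.81e-05, or 0.0349 with an estimated correlation). Among them were FGF12 (-2.15 ± 0.074), NPPA, which encodes atrial natriuretic peptide (-1.99 ± 0.079, 1553 ± 39.5 to 389.6 ± 59.0 CPM), and NPPB (-1.10 ± 0.12). Smooth muscle genes fell (12 fell of 13, median -0.81, camera adjusted p = 1.55e-11, or 0.0349 with an estimated correlation). Among them were DES, MYLK (-1.15 ± 0.062) and ACTA2 (-1.10 ± 0.073). Every measured G2/M and mitosis gene fell (26 fell of 26, median -0.93, camera adjusted p = 1.62e-17, or 0.0349 with an estimated correlation). Among them were ANLN (-1.48 ± 0.062), cyclin gene CCNA2 (-1.44 ± 0.11) and TOP2A (-0.75 ± 0.059). Genes of oxidative phosphorylation also fell (31 fell of 37, 32 fell adjusted over the list alone, median -0.45, camera adjusted p = 1.35e-11, or 0.318 with an estimated correlation). Among them were NDUFB5 (-1.02 ± 0.064), the cytochrome c gene CYCS (-0.61 ± 0.050) and COX5A (-0.85 ± 0.071).

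HOPX, a homeodomain-only cardiac gene, had the lowest fold change within these limits (-4.09 ± 0.13, 39.6 ± 2.11 to 2.27 ± 0.516 CPM), followed by GSG1 (-3.78 ± 0.29) and VAT1L (-3.53 ± 0.19). Then came the sodium and glucose cotransporter gene SLC5A1 (-3.31 ± 0.091), CYP26B1, which clears retinoic acid (-3.21 ± 0.20), NKX2-5 itself and the claudin gene CLDN6 (-3.11 ± 0.30). HOPX and VAT1L carry the 3′ UTR word GTGAACT, whose carriers were lower as a group. The genes that rose most were GRIA1, a glutamate receptor subunit (4.44 ± 0.40, 0.229 ± 0.199 to 5.05 ± 1.08 CPM), BEX5 (4.33 ± 0.31) and the lipid transporter gene MFSD2A (3.75 ± 0.24). Then came CNNM1 (3.27 ± 0.27), ECE2 (2.86 ± 0.25), C11orf87 (2.81 ± 0.092) and ACSS1 (2.72 ± 0.21). In SCR GRIA1 lies below 3 counts in a library, so the size of its fold change is uncertain. Neural genes rose (8 rose and 1 fell of 11, median 0.99, camera adjusted p = 0.00254, or 0.0508 with an estimated correlation). SNAP25 was at 1.18 ± 0.11, GAP43 at 0.99 ± 0.092 and STMN2 at 1.16 ± 0.13. Cholesterol synthesis genes rose (15 rose and 3 fell of 21, 15 rose and 4 fell adjusted over the list alone, median 0.44, camera adjusted p = 0.000326, or 0.230 with an estimated correlation), though MSMO1 fell (-1.39 ± 0.066). Cardiac stress markers fell (13 fell of 15, median -0.89, adjusted p = 6.61e-10) and G1/S and DNA replication genes fell (20 fell of 24, median -0.60, adjusted p = 5.30e-09). Fatty acid oxidation genes fell (1 rose and 20 fell of 26, median -0.38, adjusted p = 3.42e-06) and YAP targets fell (1 rose and 12 fell of 16, median -0.43, adjusted p = 6.02e-06). Glycolysis genes fell (4 rose and 13 fell of 20, median -0.33, adjusted p = 0.000118) and ventricular-enriched genes fell (3 rose and 8 fell of 12, median -0.49, adjusted p = 0.00135). Calcium handling genes fell (1 rose and 11 fell of 15, median -0.22, adjusted p = 0.00186) and cardiac transcription factors fell (4 rose and 14 fell of 27, median -0.16, adjusted p = 0.0127). Cell adhesion and intercalated disc genes fell (5 rose and 10 fell of 18, 5 rose and 11 fell adjusted over the list alone, median -0.26, adjusted p = 0.0194). With an estimated correlation, adjusted p ran from 0.0508 to 0.514 for these. Without NKX2-5 the cardiac transcription factor list still fell (adjusted p = 0.0460, or 0.353 with an estimated correlation). Among members of these lists, the ventricular repressor gene HEY2 (-1.91 ± 0.096), the calcium buffer gene CASQ2 (-1.67 ± 0.058) and LDHA (-1.93 ± 0.073) fell. The test called 7624 genes, 3775 higher and 3849 lower, 1211 of them by at least 2-fold.

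HAND1 is a helix-loop-helix factor of the developing ventricle, and the comparison asks what changes when it is low. Smooth muscle genes fell (1 rose and 12 fell of 13, median -0.92, camera adjusted p = 1.96e-11, or 0.0349 with an estimated correlation). Myosin light chain kinase MYLK was at -1.38 ± 0.063, DES at -1.57 ± 0.083 and CALD1 at -0.78 ± 0.057. Sarcomere genes fell (17 fell of 25, median -0.27, camera adjusted p = 1.44e-07, or 0.315 with an estimated correlation). Among them were the myosin genes MYH7 (-1.5 ± 0.079, 9881 ± 954 to 3487 ± 145 CPM) and MYL3 (-1.37 ± 0.093). BMP targets rose (8 rose and 1 fell of 13, 8 rose and 2 fell adjusted over the list alone, median 0.40, camera adjusted p = 0.00450, or 0.244 with an estimated correlation). BMP4 was at 1.88 ± 0.079, ID1 at 1.95 ± 0.17 and SMAD7 at 0.70 ± 0.083. Cell cycle genes fell in the G1/S and DNA replication list (19 fell of 24, median -0.37, camera adjusted p = 2.11e-06, or 0.261 with an estimated correlation). MCM6 was at -0.67 ± 0.067. They also fell in the G2/M and mitosis list (16 fell of 26, 17 fell adjusted over the list alone, median -0.35, camera adjusted p = 6.02e-06, or 0.246 with an estimated correlation). BUB1 was at -1.10 ± 0.072.

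Besides HAND1, the genes that fell most were the collagen genes COL15A1 (-3.44 ± 0.22, 12.0 ± 1.72 to 1.10 ± 0.404 CPM) and COL8A1 (-3.10 ± 0.37), CEMIP, which acts on hyaluronan (-3.27 ± 0.23), the carboxypeptidase gene CPA4 (-2.98 ± 0.30), the fatty acid elongase gene ELOVL7 (-2.60 ± 0.24) and the potassium channel gene KCNK6 (-2.33 ± 0.11). COL8A1 carries the 3′ UTR word GAGCATT, whose carriers were lower as a group. Highest were GHRH, growth hormone releasing hormone (2.55 ± 0.17, 4.71 ± 1.02 to 27.3 ± 1.27 CPM), the synaptic gene LRRTM3 (2.54 ± 0.10) and coagulation factor F10 (2.21 ± 0.15). Next were PLEKHB1 (1.99 ± 0.12), ID1, RGS9 (1.94 ± 0.23) and BMP4. Cardiac stress markers fell (2 rose and 11 fell of 15, 2 rose and 12 fell adjusted over the list alone, median -0.54, adjusted p = 5.84e-05) and calcium handling genes fell (10 fell of 15, 11 fell adjusted over the list alone, median -0.25, adjusted p = 0.000118). Ventricular-enriched genes fell (1 rose and 7 fell of 12, median -0.30, adjusted p = 0.000356) and TGF-beta targets fell (2 rose and 9 fell of 17, median -0.31, adjusted p = 0.00607). Ribosomal proteins fell (14 fell of 33, median -0.18, adjusted p = 0.0136) and YAP targets fell (3 rose and 10 fell of 16, 4 rose and 10 fell adjusted over the list alone, median -0.35, adjusted p = 0.0229). Natriuretic and secreted cardiac factors fell (5 fell of 9, median -0.25, adjusted p = 0.0274) and collagen and fibroblast genes fell (1 rose and 9 fell of 21, median -0.48, adjusted p = 0.0353). Cell adhesion and intercalated disc genes fell (4 rose and 9 fell of 18, median -0.19, adjusted p = 0.0361) and cardiac ion channels fell (3 rose and 10 fell of 22, 3 rose and 11 fell adjusted over the list alone, median -0.20, adjusted p = 0.0470). Their adjusted p ran from 0.139 to 0.812 with an estimated correlation. Without HAND1 the ventricular-enriched list still fell (adjusted p = 0.00547, or 0.198 with an estimated correlation). Within the called lists the YAP and TGF-beta target CCN2 (-1.10 ± 0.099), the gap junction gene GJA1 (-1.24 ± 0.077) and SPARC (-0.62 ± 0.067) fell. In all 6697 genes passed, 3316 higher and 3381 lower, 878 of them by at least 2-fold.

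The IRX4 comparison asks which genes follow this ventricular repressor. The G2/M and mitosis genes fell (26 fell of 26, median -0.89, camera adjusted p = 2.16e-26, or 0.0112 with an estimated correlation). ANLN was at -1.23 ± 0.062, the mitotic kinase CDK1 at -1.59 ± 0.11 and TOP2A at -0.79 ± 0.060. Targets of p53 rose (15 rose and 1 fell of 20, 17 rose and 1 fell adjusted over the list alone, median 0.44, camera adjusted p = 6.01e-08, or 0.0207 with an estimated correlation). Among them were RRM2B (0.89 ± 0.087), the death receptor gene TNFRSF10B (0.48 ± 0.052) and AEN (0.66 ± 0.074). Hypoxia response genes fell (1 rose and 12 fell of 20, median -0.30, camera adjusted p = 5.98e-05, or 0.0349 with an estimated correlation). The glucose transporter gene SLC2A3 was at -1.05 ± 0.076, P4HA2 at -0.65 ± 0.076 and VEGFA at -0.47 ± 0.056. The ventricular-enriched list, which holds IRX4 itself, was called with it (2 rose and 5 fell of 12, 2 rose and 6 fell adjusted over the list alone, median -0.18, camera adjusted p = 0.0472, or 0.372 with an estimated correlation) and not without it (median -0.17, camera adjusted p = 0.235). Single members fell, among them HEY2 (-1.25 ± 0.090, 32.7 ± 1.96 to 13.6 ± 1.87 CPM) and LBH (-0.76 ± 0.059).

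Lowest within the limits given above were ALAS2, a heme synthesis gene of red cell precursors (-2.35 ± 0.11, 43.6 ± 0.844 to 8.57 ± 2.36 CPM), DTD2 (-2.29 ± 0.15) and the mitochondrial adenylate kinase gene AK4 (-2.29 ± 0.081). Then came the lipid kinase gene DGKB (-2.02 ± 0.25), IRX4, the adaptor gene CRK (-1.86 ± 0.081) and PPIL1 (-1.84 ± 0.075). ALAS2 was higher in SCR than in NOSI by 0.92 ± 0.096, and DTD2, AK4 and CRK carry the 3′ UTR word CTCAGTC, whose carriers were lower as a group. Highest were HJV, a BMP co-receptor (2.55 ± 0.26, 1.02 ± 0.199 to 6.13 ± 1.04 CPM), the phosphatase gene PTPRZ1 (1.94 ± 0.27) and galectin LGALS1 (1.76 ± 0.11). Then came SMOC1 (1.70 ± 0.23), GHRH (1.61 ± 0.19), DHRS9 (1.59 ± 0.069) and GABRP (1.42 ± 0.25). G1/S and DNA replication genes fell (1 rose and 19 fell of 24, median -0.40, adjusted p = 1.26e-07) and ribosomal proteins rose (17 rose of 33, 22 rose adjusted over the list alone, median 0.21, adjusted p = 2.55e-06). Glycolysis genes fell (2 rose and 11 fell of 20, median -0.19, adjusted p = 0.0175). With an estimated correlation, adjusted p ran from 0.221 to 0.700 for these. Members were RRM2 (-1.30 ± 0.098), RPS19 (0.71 ± 0.081) and LDHA (-0.64 ± 0.068). The test called 5526 genes, 2754 higher and 2772 lower, 439 by at least 2-fold. IRX4 replicate 3 lay apart from the other IRX4 libraries, with a chi-square of up to 10.6 per degree of freedom between libraries of this group, and without it the count was 4613.

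MEF2C is a MADS-box factor that drives muscle genes, and in its knockdown cell cycle genes went up rather than down. G2/M and mitosis genes rose (19 rose of 26, 23 rose adjusted over the list alone, median 0.33, camera adjusted p = 3.25e-10, or 0.115 with an estimated correlation). TOP2A was at 0.47 ± 0.057 (149 ± 4.80 to 206 ± 14.9 CPM), CENPF at 0.59 ± 0.083 and PRC1 at 0.51 ± 0.072. Likewise, G1/S and DNA replication genes rose (13 rose and 1 fell of 24, 14 rose and 1 fell adjusted over the list alone, median 0.23, camera adjusted p = 0.000627, or 0.416 with an estimated correlation). CDT1 was at 0.63 ± 0.13 and MCM2 at 0.36 ± 0.075. Targets of p53 fell (1 rose and 10 fell of 20, 1 rose and 11 fell adjusted over the list alone, median -0.27, camera adjusted p = 7.56e-05, or 0.0622 with an estimated correlation). Among them were the cell cycle inhibitor gene CDKN1A (-0.49 ± 0.057), SESN2 (-0.49 ± 0.078) and DDB2 (-0.43 ± 0.087). Lysosome genes fell (8 fell of 25, median -0.063, camera adjusted p = 0.00317, or 0.256 with an estimated correlation). CTSA was at -0.61 ± 0.063 and CTSL at -0.50 ± 0.066.

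Among the genes that rose most were the sorting receptor gene SORCS1 (1.74 ± 0.15, 6.58 ± 0.351 to 22.1 ± 2.57 CPM) and GABRP (1.58 ± 0.25). Next were PCBP3 (1.53 ± 0.23), ZNF469 (1.51 ± 0.22), RASL11A (1.47 ± 0.22) and IQGAP2 (1.44 ± 0.26). Those that fell most after MEF2C were EBPL (-2.40 ± 0.22, 8.44 ± 1.21 to 1.59 ± 0.305 CPM), CCDC69 (-1.84 ± 0.049) and ALAS2 (-1.71 ± 0.10). Next were TMEM255A (-1.55 ± 0.11), REPS2 (-1.51 ± 0.17) and COL8A1 (-1.5 ± 0.30). ALAS2 was higher in SCR than in NOSI by 0.92 ± 0.096, and EBPL, REPS2 and COL8A1 carry the 3′ UTR word AACCAGA, whose carriers were lower as a group. Single muscle genes moved both ways: DES (-0.86 ± 0.080) and GATA4 (-0.38 ± 0.051) fell, while XIRP2 rose by 0.92 ± 0.10 and the sarcomere list was not called. Against NOSI the call of RASL11A was lost (adjusted p = 0.0704). In all 3743 genes passed, 1736 higher and 2007 lower, 279 of them by at least 2-fold.

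HMGB2 binds and bends DNA and marks dividing cells, and the comparison asks what follows its loss. All measured G2/M and mitosis genes fell (26 fell of 26, median -0.92, camera adjusted p = 1.70e-44, or 0.000654 with an estimated correlation). TOP2A was at -1.0 ± 0.060 (149 ± 4.80 to 74.3 ± 7.26 CPM), ANLN at -0.93 ± 0.060 and KIF20A at -1.17 ± 0.086. Genes of G1/S and DNA replication fell (1 rose and 19 fell of 24, 1 rose and 20 fell adjusted over the list alone, median -0.42, camera adjusted p = 3.14e-14, or 0.0622 with an estimated correlation). Among them were MCM6 (-0.63 ± 0.067), MCM4 (-0.57 ± 0.062) and RRM2 (-0.84 ± 0.093). Glycolysis genes fell (12 fell of 20, 13 fell adjusted over the list alone, median -0.22, camera adjusted p = 3.09e-08, or 0.300 with an estimated correlation). LDHA was at -0.70 ± 0.068 and ENO3 at -0.67 ± 0.072. Oxidative phosphorylation genes fell too (13 fell of 37, 14 fell adjusted over the list alone, median -0.14, camera adjusted p = 3.74e-06, or 0.558 with an estimated correlation). SDHB was at -0.64 ± 0.069. Neural genes rose (5 rose and 1 fell of 11, 6 rose and 2 fell adjusted over the list alone, median 0.55, camera adjusted p = 0.0420, or 0.198 with an estimated correlation). GAP43 was at 0.96 ± 0.093 and SYP at 1.20 ± 0.25.

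Among single genes the highest fold changes belonged to KIF5A, a neuronal kinesin (1.30 ± 0.21, 2.83 ± 0.749 to 6.86 ± 0.855 CPM), the adhesion gene NEGR1 (1.27 ± 0.17) and HMCN1 (1.26 ± 0.21). Then came the neuroligin gene NLGN4X (1.20 ± 0.21), SNTB1 (1.17 ± 0.22), the axon guidance receptor gene ROBO2 (1.13 ± 0.22) and RPS6KL1 (1.06 ± 0.20). The lowest after HMGB2 were SUSD2 (-1.99 ± 0.23, 5.74 ± 0.353 to 1.44 ± 0.141 CPM), ALAS2 (-1.74 ± 0.10) and skeletal actin ACTA1 (-1.43 ± 0.22). Then came the mitotic kinase gene PBK (-1.35 ± 0.10), thymidine kinase TK1 (-1.34 ± 0.15) and the ATP-gated channel gene P2RX1 (-1.33 ± 0.16). ALAS2 was higher in SCR than in NOSI by 0.92 ± 0.096, and against NOSI the call of RPS6KL1 was lost (adjusted p = 0.115). Cardiac stress markers fell (9 fell of 15, 11 fell adjusted over the list alone, median -0.27, adjusted p = 1.53e-05) and heat shock response genes fell (9 fell of 15, 10 fell adjusted over the list alone, median -0.21, adjusted p = 3.30e-05). Cholesterol synthesis genes fell (1 rose and 10 fell of 21, 1 rose and 12 fell adjusted over the list alone, median -0.20, adjusted p = 0.000197) and sarcomere genes fell (1 rose and 12 fell of 25, 3 rose and 13 fell adjusted over the list alone, median -0.18, adjusted p = 0.000444). SOXC and progenitor factors rose (4 rose of 10, median 0.15, adjusted p = 0.00346) and lysosome genes fell (7 fell of 25, median -0.12, adjusted p = 0.00481). Epicardial genes fell (4 fell of 11, 1 rose and 4 fell adjusted over the list alone, median -0.28, adjusted p = 0.0173) and natriuretic and secreted cardiac factors fell (1 rose and 4 fell of 9, 1 rose and 5 fell adjusted over the list alone, median -0.20, adjusted p = 0.0274). ER chaperones fell (6 fell of 18, 7 fell adjusted over the list alone, median -0.057, adjusted p = 0.0420) and cardiac ion channels rose (6 rose of 22, median 0.078, adjusted p = 0.0453). COP9 signalosome genes fell (1 fell of 9, median -0.12, adjusted p = 0.0464) and ribosomal proteins rose (5 rose and 1 fell of 33, 6 rose and 1 fell adjusted over the list alone, median 0.11, adjusted p = 0.0464). Cardiac transcription factors rose (7 rose of 27, median 0.099, adjusted p = 0.0473). Their adjusted p ran from 0.0508 to 0.832 with an estimated correlation. Their members included NPPB (-1.10 ± 0.12), DES (-1.0 ± 0.081) and SOX4 (0.67 ± 0.059). The test called 3122 genes, 1354 higher and 1768 lower, 166 by at least 2-fold.

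SOX11 acts in progenitor cells, and its knockdown gave the third smallest response of the 9. G1/S and DNA replication genes fell (1 rose and 14 fell of 24, 1 rose and 18 fell adjusted over the list alone, median -0.32, camera adjusted p = 2.27e-08, or 0.191 with an estimated correlation). Among them were the helicase subunits MCM6 (-0.55 ± 0.066), MCM3 (-0.37 ± 0.061) and MCM4 (-0.35 ± 0.061). YAP targets fell (1 rose and 9 fell of 16, 2 rose and 9 fell adjusted over the list alone, median -0.22, camera adjusted p = 7.45e-06, or 0.188 with an estimated correlation). Among them were DLC1 (-0.46 ± 0.057), ANKRD1 (-0.53 ± 0.078) and CCN2 (-0.62 ± 0.097). BMP targets fell (7 fell of 13, 8 fell adjusted over the list alone, median -0.34, camera adjusted p = 0.000141, or 0.139 with an estimated correlation). BMP2 was at -0.45 ± 0.064 and SMAD6 at -0.38 ± 0.068. Further, collagen and fibroblast genes fell (1 rose and 9 fell of 21, 1 rose and 11 fell adjusted over the list alone, median -0.30, camera adjusted p = 0.000172, or 0.322 with an estimated correlation). VIM was at -0.40 ± 0.067, POSTN at -1.20 ± 0.21 and MFAP5 at -1.12 ± 0.22. Cholesterol synthesis genes rose (7 rose of 21, median 0.13, camera adjusted p = 0.000141, or 0.209 with an estimated correlation). INSIG1 rose by 0.35 ± 0.049. Lysosome genes rose (7 rose of 25, 11 rose adjusted over the list alone, median 0.11, camera adjusted p = 0.000167, or 0.161 with an estimated correlation). CTSA rose by 0.60 ± 0.060.

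After SOX11 the lowest fold changes were those of KREMEN1, a receptor that restrains Wnt signalling (-2.23 ± 0.074, 67.5 ± 1.60 to 14.4 ± 1.19 CPM), LDLRAD3 (-1.74 ± 0.12) and the nucleotidase gene CANT1 (-1.70 ± 0.079). Next were HIGD2A (-1.68 ± 0.13), the sulfotransferase gene SULT1E1 (-1.56 ± 0.19) and ACTR2, a subunit of the actin-branching complex (-1.46 ± 0.061). KREMEN1, LDLRAD3 and CANT1 carry the 3′ UTR word GTGACGC, whose carriers were lower as a group. The highest were TRH, thyrotropin releasing hormone (1.36 ± 0.12, 10.3 ± 0.701 to 26.4 ± 0.925 CPM), MIR3648-2 (1.24 ± 0.18) and MIR663AHG (1.16 ± 0.14). Next were DISP2 (1.16 ± 0.23), FSD1L (1.15 ± 0.12), KIF5A (1.06 ± 0.21) and the mitochondrial carrier gene UCP2 (1.06 ± 0.077). Targets of p53 rose (6 rose and 1 fell of 20, median 0.16, adjusted p = 0.00148) and ribosomal proteins fell (6 fell of 33, median -0.10, adjusted p = 0.00194). Ventricular-enriched genes fell (1 rose and 6 fell of 12, 1 rose and 7 fell adjusted over the list alone, median -0.24, adjusted p = 0.00481) and calcium handling genes fell (2 rose and 8 fell of 15, 2 rose and 10 fell adjusted over the list alone, median -0.19, adjusted p = 0.00891). Smooth muscle genes fell (5 fell of 13, 1 rose and 7 fell adjusted over the list alone, median -0.17, adjusted p = 0.0200) and G2/M and mitosis genes fell (1 fell of 26, median -0.11, adjusted p = 0.0271). TGF-beta targets fell (5 fell of 17, 1 rose and 7 fell adjusted over the list alone, median -0.18, adjusted p = 0.0317) and cardiac stress markers fell (5 fell of 15, median -0.11, adjusted p = 0.0419). Cardiac transcription factors fell (4 fell of 27, median -0.087, adjusted p = 0.0420) and cardiac ion channels fell (1 rose and 5 fell of 22, median -0.074, adjusted p = 0.0425). With an estimated correlation, adjusted p ran from 0.161 to 0.766 for these. There CDKN1A rose by 0.44 ± 0.057, and MYL2 (-0.88 ± 0.14) and GJA1 (-0.71 ± 0.075) fell. Of the tested genes 2325 passed, 1042 higher and 1283 lower, 124 of them by at least 2-fold.

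The knockdown of SKIDA1 was the weakest, and the gene with the lowest fold change was not SKIDA1 but CTNNA1, the adhesion protein alpha-catenin (-3.40 ± 0.060, 687 ± 19.6 to 64.8 ± 9.11 CPM). Neural genes rose (2 rose of 11, 4 rose adjusted over the list alone, median 0.34, camera adjusted p = 0.00133, or 0.0480 with an estimated correlation). STMN2 was at 0.66 ± 0.14 and GAP43 at 0.41 ± 0.099. GAP43 lost its call without SCR replicate 3 (adjusted p up to 0.114). G2/M and mitosis genes fell (10 fell of 26, 18 fell adjusted over the list alone, median -0.24, camera adjusted p = 3.64e-12, or 0.0622 with an estimated correlation). ANLN was at -0.36 ± 0.059. Cardiac stress markers fell (5 fell of 15, 6 fell adjusted over the list alone, median -0.14, camera adjusted p = 1.53e-05, or 0.293 with an estimated correlation). ANKRD1 was at -0.51 ± 0.078 and FHL1 at -0.33 ± 0.057. In addition, oxidative phosphorylation genes fell (4 fell of 37, 14 fell adjusted over the list alone, median -0.13, camera adjusted p = 6.26e-08, or 0.453 with an estimated correlation). NDUFS1 was at -0.18 ± 0.043.

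Next lowest were prolidase PEPD (-1.48 ± 0.093, 61.2 ± 1.02 to 21.9 ± 1.78 CPM), CNKSR3 (-1.05 ± 0.072) and the disulfide isomerase gene PDIA4 (-1.05 ± 0.059). Then came ceramide kinase CERK (-0.97 ± 0.048), ALDH18A1, which makes a precursor of proline (-0.96 ± 0.084), and the centrosome gene CEP120 (-0.91 ± 0.10). ALDH18A1 carries the 3′ UTR word TCGTCCT, whose carriers were lower as a group. Highest were KIF5A (0.90 ± 0.22, 2.83 ± 0.749 to 5.21 ± 0.698 CPM), RIMBP2 (0.90 ± 0.19) and LINC02593 (0.86 ± 0.13). Then came SERTM1 (0.86 ± 0.16), GPR137C (0.85 ± 0.17), CLDN6 (0.84 ± 0.17) and the neural adhesion gene L1CAM (0.81 ± 0.19). KIF5A lost its call without SCR replicate 2 or SKIDA1 replicate 3 (adjusted p up to 0.0791) and L1CAM without SCR replicate 3 or SKIDA1 replicate 1 (adjusted p up to 0.0869). YAP targets fell (3 fell of 16, 1 rose and 5 fell adjusted over the list alone, median -0.081, adjusted p = 0.00148) and lysosome genes fell (6 fell of 25, 7 fell adjusted over the list alone, median -0.063, adjusted p = 0.00284). Heat shock response genes fell (1 fell of 15, 5 fell adjusted over the list alone, median -0.11, adjusted p = 0.00483) and ubiquitin and proteasome genes fell (0 of 31 passed, median -0.066, adjusted p = 0.00580). ATF4 and amino acid response genes fell (3 fell of 20, 5 fell adjusted over the list alone, median -0.18, adjusted p = 0.00820) and calcium handling genes fell (1 rose and 3 fell of 15, median -0.060, adjusted p = 0.0120). Targets of p53 fell (3 fell of 20, median -0.094, adjusted p = 0.0175) and glycolysis genes fell (2 fell of 20, 3 fell adjusted over the list alone, median -0.10, adjusted p = 0.0232). SOXC and progenitor factors rose (2 rose of 10, median 0.091, adjusted p = 0.0256) and smooth muscle genes fell (0 of 13 passed, median -0.12, adjusted p = 0.0326). Atrial-enriched genes rose (2 rose of 13, 6 rose adjusted over the list alone, median 0.076, adjusted p = 0.0378) and Wnt targets rose (0 of 12 passed, median 0.11, adjusted p = 0.0420). Their adjusted p ran from 0.161 to 0.720 with an estimated correlation. In all 844 genes passed, 377 higher and 467 lower, 29 by at least 2-fold. The count was 536 without SCR replicate 1, 521 without SKIDA1 replicate 1 and 527 without SKIDA1 replicate 2, and against NOSI it was 1377, of which 504 were among the 844.

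COPS2 kept the lowest share of its mRNA of the 9 targets, yet its knockdown changed the fewest genes of the 9. Inflammatory NF-kB targets rose (2 rose of 12, 3 rose adjusted over the list alone, median 0.44, camera adjusted p = 0.000167, or 0.0508 with an estimated correlation). NFKBIA, an inhibitor of NF-kB, was at 0.50 ± 0.090 and the chemokine gene CCL2 at 2.25 ± 0.43 (0.613 ± 0.371 to 3.03 ± 0.802 CPM). Cholesterol synthesis genes rose (3 rose of 21, 7 rose adjusted over the list alone, median 0.10, camera adjusted p = 2.38e-06, or 0.123 with an estimated correlation). INSIG1 was at 0.31 ± 0.049. Cardiac stress markers rose (2 rose of 15, 6 rose adjusted over the list alone, median 0.12, camera adjusted p = 3.01e-05, or 0.303 with an estimated correlation). FHL1 was at 0.24 ± 0.057 and SYNPO2L at 0.21 ± 0.056. FHL1 lost its call without COPS2 replicate 1 or 2 or SCR replicate 1 (adjusted p up to 0.145) and SYNPO2L without COPS2 replicate 1 or 2 or SCR replicate 1 or 3 (adjusted p up to 0.262). Of the COP9 signalosome list COPS2 alone passed the test (1 fell of 9, median -0.045, camera adjusted p = 0.00427, or 0.325 with an estimated correlation), and without COPS2 the list was not called (median -0.043, camera adjusted p = 0.668).

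Highest were ANKRD33B (0.97 ± 0.20, 2.91 ± 0.352 to 5.71 ± 0.908 CPM), ZNF469 (0.84 ± 0.23) and the G protein gene GNAZ (0.84 ± 0.22). Next were the kinase genes FRK (0.81 ± 0.20) and NUAK1 (0.64 ± 0.065), DTX4 (0.68 ± 0.11) and MEMO1 (0.66 ± 0.14). Among the lowest after COPS2 were C11orf87 (-0.86 ± 0.14) and PCOLCE2, which aids collagen processing (-0.78 ± 0.18). Next were the serpin gene SERPINI1 (-0.74 ± 0.074), ZNF225 (-0.71 ± 0.18) and the splicing factor gene SRRM4 (-0.68 ± 0.19). G2/M and mitosis genes rose (0 of 26 passed, median 0.074, adjusted p = 0.0102) and TGF-beta targets rose (1 rose of 17, median 0.087, adjusted p = 0.0120). Smooth muscle genes rose (2 rose of 13, median 0.049, adjusted p = 0.0124) and heat shock response genes fell (1 fell of 15, 5 fell adjusted over the list alone, median -0.047, adjusted p = 0.0205). Targets of p53 fell (0 of 20 passed, 4 fell adjusted over the list alone, median -0.12, adjusted p = 0.0473) and immediate early genes rose (0 of 19 passed, 1 rose adjusted over the list alone, median 0.16, adjusted p = 0.0498). With an estimated correlation, adjusted p ran from 0.265 to 0.642 for these. DES was at 0.39 ± 0.077 and HSPA8 at -0.18 ± 0.049. In all 355 genes passed, 197 higher and 158 lower, 10 by at least 2-fold. Leaving out 1 library gave 165 to 244 genes. ZNF469 lost its call without COPS2 replicate 1 or 2 or 3 or SCR replicate 1 or 2 or 3 (adjusted p up to 0.232) and GNAZ without COPS2 replicate 2 or 3 or SCR replicate 1 (adjusted p up to 0.291). FRK lost its call without COPS2 replicate 2 or SCR replicate 1 or 2 or 3 (adjusted p up to 0.103) and MEMO1 without COPS2 replicate 3 (adjusted p up to 0.0659). PCOLCE2 lost its call without COPS2 replicate 1 or SCR replicate 2 (adjusted p up to 0.110). ZNF225 lost its call without COPS2 replicate 1 or 3 or SCR replicate 1 or 2 or 3 (adjusted p up to 0.190) and SRRM4 without COPS2 replicate 2 or 3 or SCR replicate 1 or 3 (adjusted p up to 0.240). HSPA8 lost its call without COPS2 replicate 1 or 2 or 3 or SCR replicate 2 or 3 (adjusted p up to 0.197). Against NOSI 105 of the 355 genes were called again, and of the highest and lowest genes named above only FRK and NUAK1 kept their call, while FHL1 was at -0.087 (adjusted p = 0.457). The calls of DES (0.12, adjusted p = 0.445), SYNPO2L (0.099, adjusted p = 0.377) and HSPA8 (-0.051, adjusted p = 0.653) were lost too.

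Transfection with the scrambled siRNA asks for the effect of the procedure itself, and it changed few genes. Skeletal muscle genes were lower in SCR than in NOSI (3 fell of 6, 4 fell adjusted over the list alone, median -0.34, camera adjusted p = 0.000265, or 0.0508 with an estimated correlation). MYH3 was at -1.07 ± 0.24, CKM at -0.36 ± 0.081 and TNNT1 at -0.33 ± 0.086. Cardiac stress markers were lower (2 fell of 15, 1 rose and 5 fell adjusted over the list alone, median -0.19, camera adjusted p = 2.56e-05, or 0.300 with an estimated correlation). FHL1 was at -0.33 ± 0.057 and XIRP2 at -0.40 ± 0.10. Epicardial genes were higher (2 rose of 11, median 0.31, camera adjusted p = 0.00106, or 0.161 with an estimated correlation). SEMA3D was at 0.70 ± 0.12 and LRRN4 at 0.50 ± 0.11. MYH3 lost its call without NOSI replicate 2 or SCR replicate 1 or 2 (adjusted p up to 0.180) and CKM without NOSI replicate 2 or 3 or SCR replicate 1 or 2 (adjusted p up to 0.120). TNNT1 lost its call without NOSI replicate 2 or 3 or SCR replicate 1 or 2 (adjusted p up to 0.279) and XIRP2 without NOSI replicate 1 or 2 or 3 or SCR replicate 1 or 2 or 3 (adjusted p up to 0.219). LRRN4 lost its call without NOSI replicate 3 or SCR replicate 2 (adjusted p up to 0.157). Sarcomere genes fell (1 rose and 2 fell of 25, 1 rose and 7 fell adjusted over the list alone, median -0.056, adjusted p = 0.00148) and YAP targets rose (3 rose of 16, 4 rose adjusted over the list alone, median 0.12, adjusted p = 0.00240). Targets of p53 rose (1 rose of 20, 2 rose adjusted over the list alone, median 0.090, adjusted p = 0.00684) and G1/S and DNA replication genes fell (0 of 24 passed, median -0.052, adjusted p = 0.0438). Cell adhesion and intercalated disc genes rose (0 of 18 passed, median 0.067, adjusted p = 0.0470). Their adjusted p ran from 0.221 to 0.655 with an estimated correlation.

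Highest in SCR were the laminin gene LAMA1 (1.01 ± 0.15, 8.30 ± 0.246 to 16.7 ± 2.90 CPM), ALAS2 (0.92 ± 0.096) and CD274, which encodes PD-L1 (0.80 ± 0.21). Then came MEGF11 (0.74 ± 0.18), PCDHAC1 (0.70 ± 0.13), the decoy receptor gene TNFRSF10D (0.70 ± 0.16) and SEMA3D. Lowest were NRAP, a myofibril anchoring gene (-0.88 ± 0.21), MYADML2 (-0.72 ± 0.16) and BCYRN1 (-0.71 ± 0.16). Then came MST1 (-0.67 ± 0.16), ALDH16A1 (-0.67 ± 0.15), MYL2 (-0.61 ± 0.14) and CCDC77 (-0.59 ± 0.16). In all 240 genes passed, 167 higher and 73 lower. The count was 443, 54 and 54 without NOSI replicates 1, 2 and 3, 62 and 93 without SCR replicates 1 and 2, and 400 with the replicate number as a block. CD274 lost its call without NOSI replicate 2 or 3 or SCR replicate 1 or 2 or 3 (adjusted p up to 0.375), MEGF11 without NOSI replicate 3 or SCR replicate 1 or 2 (adjusted p up to 0.218) and TNFRSF10D without NOSI replicate 3 or SCR replicate 1 or 2 (adjusted p up to 0.276). NRAP lost its call without NOSI replicate 2 or 3 or SCR replicate 1 or 2 (adjusted p up to 0.156) and MYADML2 without NOSI replicate 2 or 3 or SCR replicate 1 (adjusted p up to 0.112). BCYRN1 lost its call without NOSI replicate 2 or 3 or SCR replicate 2 (adjusted p up to 0.125) and MST1 without NOSI replicate 2 or 3 or SCR replicate 1 or 2 (adjusted p up to 0.231). ALDH16A1 lost its call without NOSI replicate 2 or SCR replicate 1 (adjusted p up to 0.121) and MYL2 without NOSI replicate 2 or 3 or SCR replicate 1 or 2 (adjusted p up to 0.174). CCDC77 lost its call without NOSI replicate 2 or 3 or SCR replicate 1 or 2 or 3 (adjusted p up to 0.278).

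**Figure D3:**
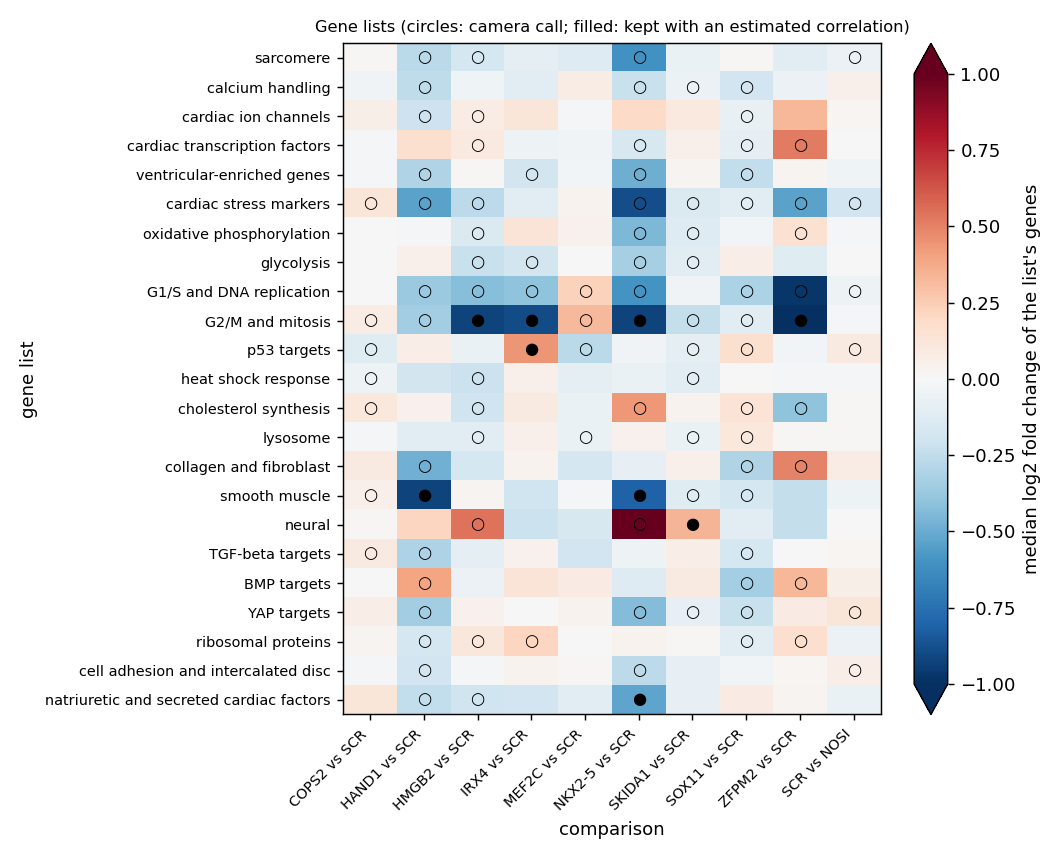
Median log2 fold change of the genes of 23 lists (vertical axis) in the 10 comparisons (horizontal axis), as colours limited to 1 in either direction. Circles mark lists called by camera and filled circles those kept with an estimated correlation, and the G2/M and mitosis list runs from -2.15 for ZFPM2 to 0.33 for MEF2C.

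Over the 10 comparisons 122 of 430 list tests were called, and in each of them the median, the mean and the test had the same sign. With the silenced gene taken out of its own lists, 119 were called. With a correlation estimated for each list 10 of these calls held: smooth muscle in the HAND1 and NKX2-5 knockdowns, G2/M and mitosis in the HMGB2, IRX4, NKX2-5 and ZFPM2 knockdowns, p53 targets and hypoxia response in the IRX4 knockdown, natriuretic and secreted cardiac factors in the NKX2-5 knockdown and neural genes in the SKIDA1 knockdown. The lists called in none of the 10 comparisons were HMG-box and high mobility group, NRF2 targets, endoderm and hepatic, endothelial, interferon response and pluripotency. Single members of each of these lists still changed in some comparison, and the mitochondrially encoded mRNAs had 0 counts in every library, so that list was not tested.

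**Figure D4:**
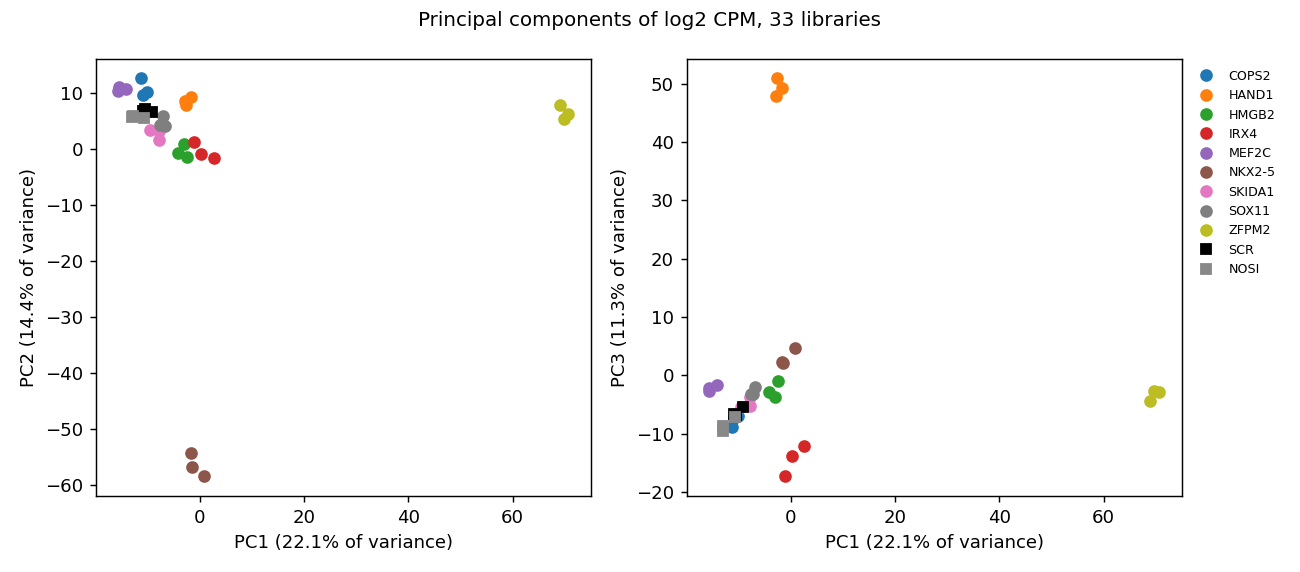
Principal components of the log2 CPM of all 33 libraries, with 1 point per library coloured by group, and with the share of variance on each axis (22.1% for the first, 14.4% for the second and 11.3% for the third). The ZFPM2 libraries stand apart on the first component, NKX2-5 on the second and HAND1 on the third.

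In at least 5 of the 9 knockdowns 911 genes changed the same way, 291 higher and 620 lower, where 62.3 would be reached if the 9 sets of calls were independent. The 7 lowest by mean log2 fold change were ALAS2 (-1.39 ± 0.068), GSG1 (-1.26 ± 0.15), CEMIP (-1.12 ± 0.12), the natriuretic peptide clearance receptor gene NPR3 (-1.09 ± 0.20), COL8A1 (-1.03 ± 0.20), COL15A1 (-1.02 ± 0.11) and the matrix gene POSTN (-0.98 ± 0.14). ALAS2 stood at 43.6 CPM in SCR, 23.0 in NOSI and 19.9 on average in the 9 knockdowns. The 7 highest were LRRTM3 (0.80 ± 0.097), GNAZ (0.74 ± 0.17), LIX1 (0.73 ± 0.095), CASC9 (0.68 ± 0.15), PLEKHB1 (0.67 ± 0.11), SLC35D3 (0.67 ± 0.17) and ZNF587B (0.65 ± 0.15). Against SCR and NOSI, GNAZ was higher in 6 and 1 knockdowns, ZNF587B in 5 and 1, CASC9 in 6 and 2, PLEKHB1 in 5 and 3, SLC35D3 in 5 and 5, LRRTM3 in 5 and 6 and LIX1 in 5 and 8. NPR3 was lower in 6 and 2, COL8A1 in 5 and 3, POSTN in 6 and 5, CEMIP in 6 and 5, GSG1 in 5 and 6, COL15A1 in 6 and 8 and ALAS2 in 8 and 6, which was higher in 3 against NOSI. The mean of the 9 knockdowns differed from SCR in 2440 genes, 713 higher and 1727 lower, and the mean of the 3 targets whose titles carry p2, as those of SCR do, in 2357 (1233 shared). Against NOSI 1385 genes changed the same way in at least 5 knockdowns, and 513 met this against both controls.

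In the mean of the 9 knockdowns 13 lists were called, all down, and 5 held with an estimated correlation. These were G2/M and mitosis (26 fell of 26, median -0.59, camera adjusted p = 7.85e-43, or 9.92e-05 with an estimated correlation) and G1/S and DNA replication (17 fell of 24, 20 fell adjusted over the list alone, median -0.32, camera adjusted p = 4.54e-16, or 0.0255 with an estimated correlation). Then came cardiac stress markers (11 fell of 15, 14 fell adjusted over the list alone, median -0.29, camera adjusted p = 2.21e-12, or 0.0433 with an estimated correlation) and smooth muscle (9 fell of 13, 11 fell adjusted over the list alone, median -0.27, camera adjusted p = 2.76e-08, or 0.0418 with an estimated correlation). The last was ventricular-enriched genes (8 fell of 12, 9 fell adjusted over the list alone, median -0.26, camera adjusted p = 5.59e-07, or 0.0198 with an estimated correlation), also without HAND1 and IRX4 (camera adjusted p = 1.06e-05). Sarcomere genes fell (14 fell of 25, 17 fell adjusted over the list alone, median -0.18, adjusted p = 6.08e-10) and calcium handling genes fell (5 fell of 15, median -0.086, adjusted p = 9.73e-05). Glycolysis genes fell (7 fell of 20, 8 fell adjusted over the list alone, median -0.060, adjusted p = 0.00114) and YAP targets fell (1 rose and 9 fell of 16, 2 rose and 10 fell adjusted over the list alone, median -0.17, adjusted p = 0.00114). Cell adhesion and intercalated disc genes fell (2 rose and 9 fell of 18, 2 rose and 10 fell adjusted over the list alone, median -0.11, adjusted p = 0.00359) and natriuretic and secreted cardiac factors fell (5 fell of 9, median -0.15, adjusted p = 0.00376). Fatty acid oxidation genes fell (5 fell of 26, 6 fell adjusted over the list alone, median -0.083, adjusted p = 0.0266) and heat shock response genes fell (3 fell of 15, 1 rose and 5 fell adjusted over the list alone, median -0.077, adjusted p = 0.0337). With an estimated correlation, adjusted p ran from 0.0690 to 0.479 for these. Across genes, which are not independent replicates, the fold changes of 2 knockdowns against the same SCR libraries had a median correlation of 0.265 over the 36 pairs (0.084 to 0.366), and 0.045 when 1 member of each pair was set against SCR and the other against NOSI.

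The titles place COPS2, HAND1, HMGB2, MEF2C, NKX2-5 and ZFPM2 under p1 and the other 5 groups under p2. All SCR libraries carry p2, and no control library carries p1, so each p1 target differs from SCR in the field too. COPS2, also p1, differed from SCR in 355 genes, which argues against a shift common to p1 as the source of most of the 6697 to 8379 genes of HAND1, NKX2-5 and ZFPM2, and other effects of the field stay open. Set against the mean of the other targets with the same field, each target still differed: 4963 genes for COPS2, 8384 for HAND1, 5207 for HMGB2, 6368 for IRX4, 6603 for MEF2C, 9218 for NKX2-5, 3833 for SKIDA1, 4520 for SOX11 and 9968 for ZFPM2. These counts hold the response to the knockdown named and, with the opposite sign, part of the responses to the others.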

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

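Chosen after the result was seen were the tests of SCR standing apart, of the title field, of each group as the control, of CTNNA1 in the other knockdowns, of fibroblast-like cells, of the highest word unlike another, of mitosis genes in counts without scaling and of the highest covariance in a round. The other tests were chosen before.

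The share of read pairs that HTSeq could not assign to a single gene lies outside the comparisons made, and in 4 groups its mean was above that of the highest control library (5.96%). These were COPS2 (6.04 ± 0.096%), IRX4 (6.02 ± 0.30%), NKX2-5 (6.10 ± 0.17%) and SOX11 (5.98 ± 0.14%). No explanation for it was tested.

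The first pattern weighed is the set of genes that fell after each siRNA, set against the siRNA acting like a microRNA on 3′ UTRs that match its seed. The word most tied to falls had t = -16.75 (HAND1), -8.32 (HMGB2), -19.18 (IRX4), -11.23 (MEF2C), -14.82 (NKX2-5), -7.26 (SKIDA1), -12.58 (SOX11) and -15.87 (ZFPM2). Carriers had median log2 fold changes of -0.273 (ZFPM2) to -0.022 (HMGB2), so seed matches may explain part of these falls, least so for HMGB2. For COPS2 the lowest word had t = -3.93, with a Bonferroni p of 1, weaker than the highest words, GTAAACC (5.13, past the Bonferroni limit) and, among words unlike it, TGTGTGT (4.77), which argues against a seed effect as strong as in the others. For SCR the lowest word was the same GTAAACC (-5.15), too close to the highest word (4.59) to decide. Its median t over the 9 knockdowns was 3.40, as an effect in the SCR libraries would give, but so would chance in libraries that all 9 share. The own mRNA of 7 of the 9 targets, all but COPS2 and IRX4, holds its word, where 1.56 would be met by chance (exact p = 5.05e-05 from the share of mRNAs of similar length that hold each word). Words past the Bonferroni limit were more common among genes that fell than among those that rose for IRX4 (77.6 and 55.7%), SOX11 (39.0 and 17.5%), SKIDA1 (17.9 and 5.00%), NKX2-5 (73.8 and 61.6%), MEF2C (63.8 and 51.1%), ZFPM2 (59.3 and 48.1%) and HAND1 (67.1 and 59.1%), and not for HMGB2 (82.8 and 85.1%). As these words were picked from the same fold changes, part of this lean is built in, and a response to the target remains possible for every gene.

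Within this pattern CTNNA1 fell by 3.40 in the SKIDA1 knockdown, further than SKIDA1. Its longest run of bases shared with the SKIDA1 mRNA was 13, and 78.4% of mRNAs of similar length share as long a run, which speaks against a long exact match but not against one with mismatches. Counts of the pseudogene CTNNA1P1 were 0.748% of those of CTNNA1, too few to explain the fall. In the 8 other knockdowns the median change was -0.088 (-0.416 to 0.099), so no common response was seen. What stays open is an oligo acting on CTNNA1 with mismatches or a response to SKIDA1, and neither was tested.

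The second pattern is the 911 genes changed the same way in at least 5 of the 9 knockdowns, all against the same 3 SCR libraries. Groups and a control without change, all simulated from the SCR mean, gave 0 such genes in each of 20 rounds of edgeR. The mean of the 9 gave at most 2 genes, against 2440 observed. As no simulated comparison called more than 3 genes, 0 shared genes was near certain. These counts do not tell what a shared control adds where groups do respond. The fold changes of the simulated groups correlated more (median 0.495) than those observed (0.265), to which the responses add variance. Their median covariance was lower (0.0263, highest round 0.0297) than that observed (0.0378). With SCR for one member of a pair and NOSI for the other the covariance was 0.00700, so the shared control accounts for much of the likeness. Calls in the same direction exceeded independence in all 36 pairs, but opposite calls did so in 19, and in 2 pairs they outnumbered those in the same direction, so a shared response beyond the control stays open. Against NOSI the signed median of the 911 was 0.265, which is 81.5% of the 0.325 against SCR, and this argues against SCR libraries that stand apart as the whole cause. The signed median was 0.061 in COPS2, 0.204 in MEF2C, 0.321 in HMGB2, 0.430 in HAND1, 0.496 in NKX2-5 and 0.646 in ZFPM2, all p1, and 0.178 in SKIDA1, 0.216 in SOX11 and 0.410 in IRX4, which carry p2 as SCR does. The value in COPS2 and those in the p2 targets argue against an equal shift of all p1 groups as the whole cause, but 4 of the 6 p1 groups lie above the p2 median (0.216), so a part due to the field stays open. A common effect of targeting siRNAs is a hypothesis only.

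The third pattern is the fall of the G2/M and mitosis list in the HMGB2 (-0.92), IRX4 (-0.89), NKX2-5 (-0.93) and ZFPM2 (-2.15) knockdowns. In counts without any scaling, 498 genes of the same SCR level outside the cell cycle lists had medians of -0.002 ± 0.013, -0.033 ± 0.017, 0.10 ± 0.024 and -0.112 ± 0.030 in these 4 (26 mitosis genes -0.927, -0.936, -0.818 and -2.25), at most 4.99% of the fall. NOSI as the control kept at least 99.5% of the fall and members without a seed word at least 89.9%, which speaks against depth or composition, the choice of control and seed matches in these genes as the whole cause. Fewer cells of a fibroblast kind would, as the whole cause, lower their own genes about as far, and the collagen and fibroblast list had medians of -0.177 ± 0.071 for HMGB2, 0.035 ± 0.133 for IRX4, -0.080 ± 0.145 for NKX2-5 and 0.495 ± 0.224 for ZFPM2, which argues against it in all 4. Of that list 21 genes were measured, 15 reached 5 CPM in SCR and 2 are in another list, and its most abundant in SCR were COL6A1 (356.0 CPM) and SPARC (337.3). A part through fewer fibroblast-like cells and a loss of dividing cells alone stay open, and a lower rate of division is a hypothesis.

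With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In fits on the 6 libraries the real split called 619 genes for COPS2 (highest other 1), 7262 for HAND1 (0), 3573 for HMGB2 (0), 3869 for IRX4 (0), 4051 for MEF2C (0), 7142 for NKX2-5 (0), 821 for SKIDA1 (1), 1995 for SOX11 (0) and 8296 for ZFPM2 (0), and 1 of the 10 splits reached that number in each. For SCR against NOSI 2 of the 10 splits reached the real count of 175, the highest other being 277, which points to a structure of these 6 libraries beyond their groups. For the mean of the 9, a fit with 1 mean per side (27 libraries against 3) called 0 genes in edgeR (435 at an unadjusted p under 0.05, and 0 in limma-voom), and the highest other split 1187. As any split reaches 0, the 100 of 100 that did say nothing about chance, and such a fit counts the differences between the 9 targets as spread. For the 911 shared genes each of the 10 transfected groups was taken as the control, and all 10 reached the count (8188 the highest, for ZFPM2). A knockdown taken as the control adds its own response, so this says nothing about chance either.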

How the results depend on the processing

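Some alternatives, named above, were chosen after the data were seen. The fall of each of the 9 targets kept its direction and its side of the threshold under every alternative run, with the widest range for MEF2C (-3.365 to -2.866). DESeq2 size factors, limma-voom and the DESeq2 Wald test left every count of changed genes within 1.5 times. So did no filter, which tests more genes. The counts for HAND1, IRX4, NKX2-5 and ZFPM2 stayed within 1.5 times under all alternatives, as did the mean of the 9 (1681 to 3156, with 1424 of the 2440 shared against NOSI and 1233 with only the p2 targets), the 27 target pairs (25 to 34) and the differences within a title field.

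With NOSI as the control SKIDA1 changed 1377 genes, 504 of them shared with SCR as the control, and 1385 genes changed in at least 5 knockdowns. COPS2 gave 448 genes, of which 105 were shared. Set against the other targets of the title field, COPS2 gave 4963 (250 shared), HMGB2 5207 (2043), MEF2C 6603 (2889), SKIDA1 3833 (510) and SOX11 4520 (1542). That comparator adds the responses of the other targets. A fit on 6 libraries gave 619 for COPS2 (347 shared), and the cause was not tested.

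The number of lists called was 10 with an estimated correlation, 187 with fry and 184 without the filter, against 122. Taking the silenced gene out of its own lists left 119 calls and ended those of the COP9 signalosome for COPS2 and of ventricular-enriched genes for IRX4. It also moved immediate early genes for COPS2, a list without COPS2, from an adjusted p of 0.0498 to 0.0506, since all tests were adjusted again. The median correlation of fold changes went from 0.265 to 0.045 with SCR for one member and NOSI for the other, and to -0.264 against the other targets of the title field, where each target is part of the others' comparator.

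The replicate number as a block gave 400 genes for SCR against NOSI and stayed within 1.5 times elsewhere. Residuals of libraries with the same number correlated by -0.027 to 0.11 in pairs with SCR. In 0 of 10 comparisons was every pair above 0.1, so the numbers were not treated as pairs.

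Leaving out 1 library gave 165 to 244 genes for COPS2 (169 without SCR replicate 1, 184 without SCR replicate 3, 179, 165 and 234 without COPS2 replicates 1, 2 and 3). For SKIDA1 it gave 521 to 709, and for SCR against NOSI 54 to 443 (by library above). Fewer samples lower the power, and the cause of the rise to 443 was not tested. The rest stayed within 1.5 times.

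Over the named genes, leaving out 1 library kept the call and direction in 5425 cases, lost the call in 358, gained one in 13 and reversed 0. NOSI as the control kept 835, lost 76, gained 6 and reversed 10, and the title-field comparator kept 760, lost 80, gained 16 and reversed 55. That comparator was not run for a gene that is another target of the same title field. No other alternative reversed a named gene. For the reversed ones the cause was not tested.

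Reversed with NOSI as the control were, in log2 fold changes, FHL1 -0.087, CCNB2 -0.15, HSPE1 0.012 and COPS7A -0.030 for COPS2, COPS2 0.007 for HMGB2, SEMA3D 0.090 for IRX4, SEMA3D 0.049 for MEF2C, and HSPA4L 0.084, NKD2 -0.20 and AXL 0.005 for SKIDA1.

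Among those reversed against the other targets of the title field were PCOLCE2 0.48, ZNF225 0.051, SESN1 0.012, COPS8 0.15 and COPS7A -0.086 for COPS2, NPPA 0.076, ANLN 0.042 and ASPM 0.13 for HAND1, DLC1 0.063 for IRX4, and MYL3 0.041 and NFKBIA -0.14 for ZFPM2. For HMGB2 they included MYL3 0.059, MYL2 0.25, ISL1 -0.12, NPPA 0.15, MYH7 0.12, CDKN1A 0.13, NFKBIA -0.062, PHGDH 0.028, MSMO1 0.15, ACTA2 0.022, CNN1 0.18, ANKRD1 0.27, PSMD1 0.043, VCL 0.057 and PARVA 0.21. For MEF2C they included DES 0.00, HOPX 0.060, CALD1 0.003, CNN1 0.18, ID1 -0.39 and NPPA 0.44. For SKIDA1 they were ACTN2 0.12, HOPX 0.010, NR2F1 -0.001, XIRP2 0.024, HK2 0.22, PDK1 0.23, ANLN 0.44, KIF23 0.30, MKI67 0.16, NKD2 -0.035, CTNNA3 0.070 and PKP2 0.008. For SOX11 they were HEY2 0.21, NR2F1 -0.10, LDHA 0.015, ALDOC -0.076, ANLN 0.42, KIF11 0.33, CDK1 0.68 and PDIA4 0.23.

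Depth limits genes near the floor, where 3 counts in a library correspond to 0.299 to 0.383 CPM.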
